A study of Mus musculus with 8 samples.

How the data were processed

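Chromatin accessibility was measured by bulk ATAC-seq with the Omni-ATAC procedure, in which the Tn5 transposase inserts sequencing adapters into open DNA and a detergent mix lowers the yield of mitochondrial reads. The samples were 2 sorted subpopulations of MPP2 cells from bone marrow of adult C57BL/6 mice aged 8 to 12 weeks, with 500 cells in each replicate and 4 replicates in each subpopulation. MPP2 cells are multipotent blood progenitors, here sorted as LSK (lineage-negative, Sca1-positive, Kit-positive) cells without Flt3 and with CD150 and CD48. Groups were taken from the cell type in the labels, Vwf+Gata1+ MPP2 or Vwf-Gata1+ MPP2, and replicate numbers from the sample titles. No label says whether the replicates came from separate animals, so p-values measure only the spread between these libraries, part of which may be technical.

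The authors deposited 1 table of raw counts, with 134473 peaks in rows and the 8 libraries in columns. Per the submitters' processing notes the build was mm9, and the tools named there were Trim Galore, FastQC, Bowtie2, SAMtools, Picard and MACS2, without versions. The notes used here give no role or order for these tools. Whether a count is a read or a fragment, whether read ends were shifted to the centre of the transposase insertion, how duplicates were treated and how peaks of different libraries were merged is not given in the sources used here. A missing shift would move a cut site by a few bases, and the peaks had a median width of 393 bp. Peak widths ran from 200 to 4022 bp, and the peaks covered 72.2 Mb. Every row named a peak and every column was used. Starts are given as in the table and were read as 1-based.

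The build was checked against the table. On 21 of 21 chromosomes the last peak ended within the mm9 chromosome length. Lengths of other mouse builds were not compared, so this check does not tell mm9 from them. The reference used here was a gene table of the GRCm38.p6 assembly, another build, and coordinates were not converted. Peaks are therefore given by mm9 position. Peaks were not assigned to genes, exons, introns or untranslated regions. The gene lists, the promoter and gene body classes, the transcription factor motifs and the peaks at Vwf and Gata1, all planned, were not analysed here.

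Total counts ran from 4628997 to 7753538 per library. Peaks with too few counts were left out with edgeR's filterByExpr, using its minimum count of 10 and minimum total of 15, which kept 97040 peaks (72.2% of peaks, 96.3% of counts). Libraries were scaled by TMM. Differences were tested with edgeR's quasi-likelihood test with robust dispersions, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All log2 fold changes are Vwf+Gata1+ minus Vwf-Gata1+, with a standard error taken as the size of the log2 fold change over the square root of the test's F statistic. Signal is given as CPM after TMM scaling, as mean ± SD over 4 libraries. Tested peaks were also divided into 3 equal classes by mean signal and 3 by width. Principal components and correlations used log2 CPM with a prior count of 2. Values of single libraries were compared between groups with 2-sided exact permutation tests, for which 4 libraries against 4 allow no p below 0.0286. Intervals of shares in single libraries are exact binomial intervals at 95% and cover counting error only. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were used.

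The test was run on simulated data with the real means, library sizes and dispersions, in which 200 of 97040 peaks were changed in each of 3 simulations per fold. It recovered 18.5% of peaks changed 1.5-fold, 54% of those changed 2-fold and 98% of those changed 4-fold. Between 5.81% and 6.72% of the calls in these simulations were false. With no peak changed it made 0 calls. These simulations used dispersions estimated without down-weighting outlying peaks, a choice made after simulations from robust estimates had given more false calls. With robust dispersions, between 7.92% and 11.1% of calls were false, and 3 simulations with no peak changed gave 7 calls in all, up to 4 in one. The false share of calls can therefore exceed the threshold of 0.05. All simulated counts were drawn independently for each peak. False calls from a structure that many peaks of a library share are therefore not covered.

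The design, the alternatives and the rule for naming peaks were fixed before the data were examined. The rule names up to 12 peaks per direction with the lowest adjusted p among those past the threshold whose groups do not overlap, with 1 peak per 100 kb. A peak ranked after these is named once and was chosen after its values were seen. The alternatives were a fit with the replicate number as a block, RLE and total count scaling, loess offsets, no filter, a minimum CPM of 1 in 4 libraries, DESeq2, limma-voom with quality weights, autosomes only, other thresholds, and each library left out in turn. Chosen after seeing the data were 2 more fits (a term for replicate 1, and the share of counts in the strongest 1% of peaks as a covariate), counts summed in windows, the neighbours of called peaks within 100 kb, runs of peaks at p under 0.01, and the share of higher peaks at p under 0.001 in each fit.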

Results

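Chromatin accessibility was profiled in 2 subpopulations of mouse MPP2 cells, 500 cells per library and 4 libraries per group. MPP2 cells are multipotent progenitors of the bone marrow with a bias toward megakaryocytes and red cells. Both subpopulations were sorted as positive for Gata1, a transcription factor of the erythroid and megakaryocyte lineages. They differed in Vwf, the gene of von Willebrand factor, which megakaryocytes, platelets and endothelium carry. The comparison asks which accessible regions differ between Vwf+Gata1+ and Vwf-Gata1+ MPP2 cells.

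Total counts in peaks were 7753538, 5632393, 4628997 and 7219910 for replicates 1 to 4 of Vwf+Gata1+ cells. They were 7670844, 6675756, 5447813 and 7095045 for replicates 1 to 4 of Vwf-Gata1+ cells. No library differed from another of its group by as little as sampling noise, with chi-square values per degree of freedom from 1.32 to 2.13 within groups, so all 8 were kept as separate samples. The strongest 1% of peaks held 11.5% ± 0.522 of counts in Vwf+Gata1+ cells and 11.1% ± 0.722 in Vwf-Gata1+ cells (SD, n = 4 each; exact permutation p = 0.457, 0.849 after adjustment over 8 tests). With this share as a covariate, a fit chosen after seeing the data, edgeR called 33 higher and 15 lower peaks, which included the 14 described here.

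Of 97040 peaks tested, 14 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 13 with higher signal in Vwf+Gata1+ cells and 1 with lower signal. Scaling by total count in place of TMM gave 21 higher and 6 lower, and loess offsets 27 and 7. A term for replicate 1, chosen after seeing the data, gave 169 and 42. The replicate number as a block, a planned fit, gave 375 and 136, although no label says that a shared number pairs the samples. At each of the 14, the 4 libraries of one group lay entirely above the 4 of the other. Peaks picked for a small p tend to separate in this way, so this is no separate support. The groups did not overlap at 3.88% of all tested peaks, where chance gives 2.86%. The fold differences at the 14 peaks ran from 1.51 to 4.37, and 10 of the 14 were 2-fold or more. No chromosome held more than 2 called peaks, so no run of 3 neighbouring called peaks was possible.

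The strongest difference was at a peak of chromosome 10 (mm9, 23479562 to 23480070). Its signal was 3.59 ± 0.489 CPM in Vwf+Gata1+ cells and 0.777 ± 0.274 CPM in Vwf-Gata1+ cells (SD, n = 4 each), a log2 fold change of 2.13 ± 0.34 (SE; edgeR adjusted p = 0.0124). Its counts were low, 17 to 27 per library in the first group and 3 to 9 in the second. On chromosome 14 the peak at 73999572 to 74000073 had 7.61 ± 1.63 CPM against 2.82 ± 0.553 CPM, a log2 fold change of 1.42 ± 0.23 (SE; edgeR adjusted p = 0.0124). On chromosome 2 the peak at 118581827 to 118582344 had 13.7 ± 4.56 CPM against 5.81 ± 1.09 CPM, a log2 fold change of 1.21 ± 0.20 (SE; edgeR adjusted p = 0.0124). The only peak with lower signal in Vwf+Gata1+ cells was on chromosome 12 (55562372 to 55562796). It had 1.12 ± 0.423 CPM in Vwf+Gata1+ cells and 3.89 ± 0.973 CPM in Vwf-Gata1+ cells, a log2 fold change of -1.85 ± 0.33 (SE; edgeR adjusted p = 0.0351).

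**Figure D1:**
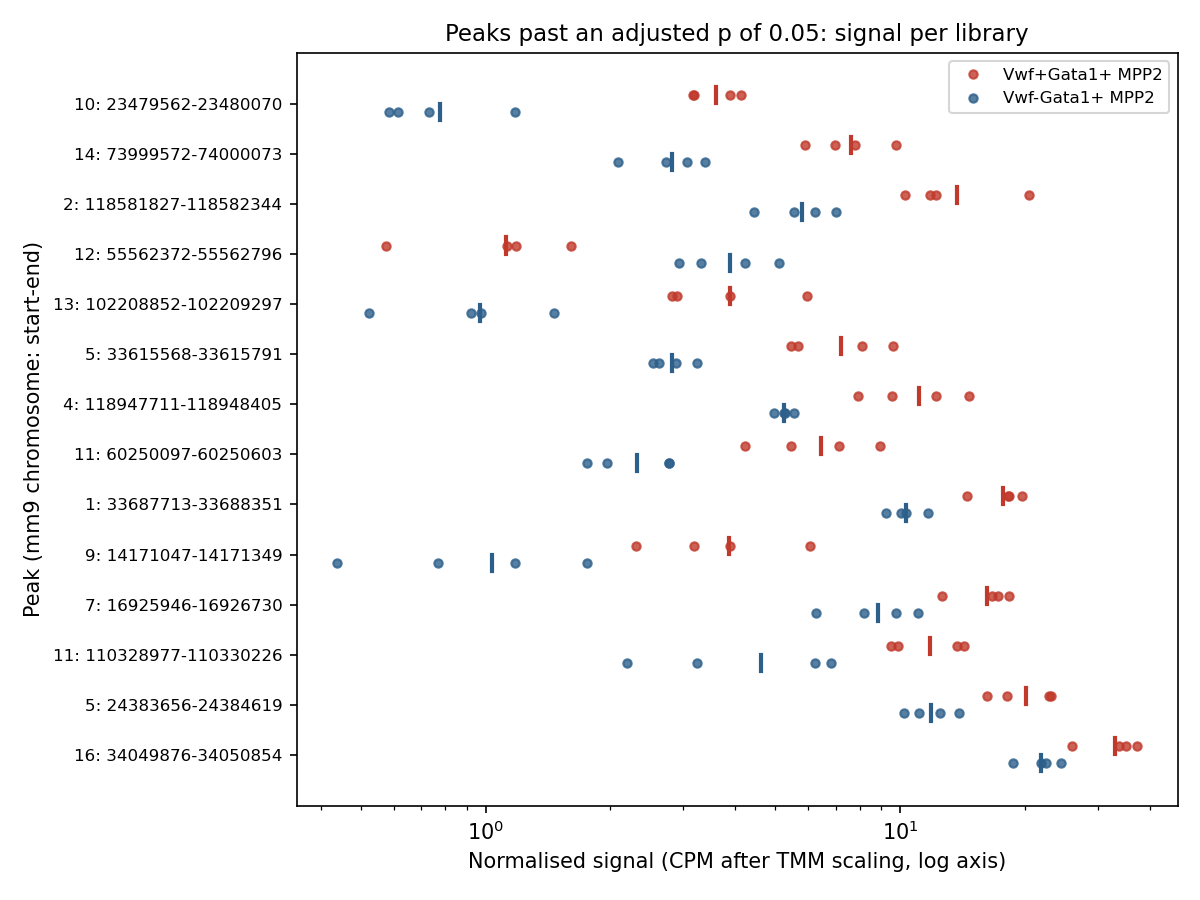
Signal of the 14 peaks past the threshold in each library, in CPM after TMM scaling on a log axis; points are libraries (4 per group), vertical bars are group means, and peaks are listed by mm9 position in order of p. The groups do not overlap at any of the 14 peaks, and the peak of chromosome 12 is the 1 with lower signal in Vwf+Gata1+ cells.

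The other peaks with over 2-fold higher signal lay on chromosomes 4, 5, 9, 11 and 13. The peaks at 102208852 to 102209297 on chromosome 13 and at 14171047 to 14171349 on chromosome 9 both had a log2 fold change of 1.95. Their signal was 3.89 ± 1.46 and 3.86 ± 1.6 CPM in Vwf+Gata1+ cells against 0.970 ± 0.384 and 1.03 ± 0.568 CPM. Counts in Vwf-Gata1+ cells were low, 4 to 10 and 3 to 9 per library. The chromosome 9 peak had 46 counts in replicate 1 of Vwf+Gata1+ cells. Without that library its log2 fold change was 1.59 (edgeR adjusted p = 0.125). A narrow peak of 224 bp on chromosome 5 (33615568 to 33615791) had 7.21 ± 2.0 CPM against 2.82 ± 0.310 CPM. Chromosome 11 held 2 called peaks. The peak at 60250097 to 60250603 had 6.44 ± 2.05 CPM against 2.31 ± 0.533 CPM, and the peak at 110328977 to 110330226, the widest of the 14 at 1250 bp, had 11.8 ± 2.5 CPM against 4.61 ± 2.25 CPM. On chromosome 4 the peak at 118947711 to 118948405 had 11.1 ± 2.98 CPM against 5.26 ± 0.233 CPM.

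The smallest changes past the threshold were at stronger peaks, where the test has more power. The peak at 16925946 to 16926730 on chromosome 7 had a log2 fold change of 0.87 ± 0.16 (SE). At 33687713 to 33688351 on chromosome 1 it was 0.77 ± 0.14, and at 24383656 to 24384619 on chromosome 5 it was 0.75 ± 0.14. A peak of chromosome 16 (34049876 to 34050854) ranked last, was outside the naming rule and was chosen after its values were seen. It had the highest signal of the 14, with 33.05 ± 4.96 CPM against 21.9 ± 2.36 CPM, and a log2 fold change of 0.59 ± 0.11 (edgeR adjusted p = 0.0486).

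**Figure D2:**
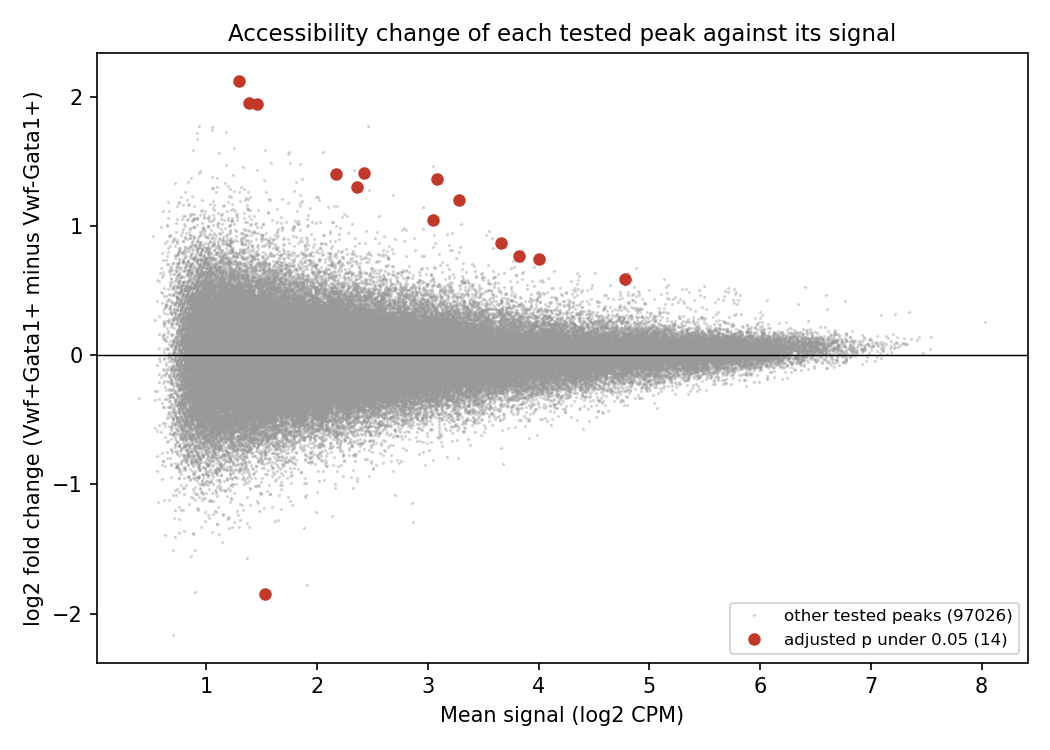
Log2 fold change (Vwf+Gata1+ minus Vwf-Gata1+) of each tested peak against its mean signal in log2 CPM; grey points are peaks that did not pass the threshold and red points the 14 that did. The called changes narrow from a log2 fold change of 2.13 at the weakest called peak to 0.59 at the strongest. A weak peak passes the threshold only with a large change, so this narrowing comes with the test.

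The signal around the called peaks was examined as a measure chosen after seeing the data. Within 100 kb of the 14 peaks lay 254 tested peaks, of which 139 (54.7%) went in the direction of their called peak. Random tested peaks gave 51.6% on average, with a central 95% range of 44.1% to 59.2%. At 7 of the 14 peaks the median change of the neighbours was away from the call. The share ran from 11 of 12 neighbours at the lower peak of chromosome 12 (median log2 change 0.10 toward the call) to 9 of 23 at the wider peak of chromosome 11 (median -0.05). At the peak of chromosome 1, 15 of 18 neighbours were also higher, and at the peak of chromosome 2, 15 of 35. The peak of chromosome 16 had 5 neighbours at an unadjusted p under 0.05 in its own direction, the most of the 14. Around the chromosome 10 peak, 5 of 10 neighbours went in its direction.

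The 14 called peaks lay on 12 chromosomes. The share of the 13 higher peaks in each chromosome, signal class and width class was set against that of the other tested peaks, and none differed past the threshold (Fisher's exact test, adjusted p = 1 in each over 54 tests). With 13 peaks these tests could detect only a strong excess, and 1 lower peak is too few for such a test. From the weakest to the strongest of 3 equal signal classes, the higher peaks numbered 3, 3 and 7, and the lower peak was in the weakest. No called peak was on chromosome X, where 2177 peaks were tested, or on Y, where 2 were tested.

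Beyond the threshold, 6522 peaks had an unadjusted p under 0.05, where uniform p-values would give 4852. Of the other ways to split the 8 libraries into 4 and 4, 8 gave more such peaks, up to 10050. All of these kept both replicate 1 libraries on one side. The other splits that part them, as the real one does, gave at most 5060, a subset chosen after the counts were seen. At an unadjusted p under 0.001 there were 327 peaks, 212 higher and 115 lower, where uniform p-values would give 97. The groups did not overlap at 3765 peaks, which is 3.88% of those tested, where chance gives 2.86%. The estimated share of unchanged peaks was 93.9%. This estimate takes p-values of unchanged peaks to be uniform and was not made for the other splits. Since some of those gave more small p-values, it does not count peaks that differ by the sort. For 83022 peaks (85.6%), the 95% interval of the fold change lay within 2-fold in either direction. That share was 63.5%, 93.6% and 99.6% from the weakest to the strongest signal class, so 2-fold changes often could not be excluded at this depth among weak peaks. These intervals are not adjusted for the number of tests and do not say which changes the threshold could call. In the simulations, 54% of peaks changed 2-fold were called, over all signal classes.

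Larger regions were compared by summing counts in windows, also chosen after seeing the data. In 10 kb windows edgeR called 6 of 65335 as higher and 0 as lower, with 4633 at an unadjusted p under 0.05. A window of chromosome 16 (94910001 to 94920000) was among these 6 although none of the 14 peaks lay in it. It was chosen after its values were seen, held 2 peaks and had a log2 fold change of 0.50 ± 0.09 (SE; edgeR adjusted p = 0.047). In 100 kb windows edgeR called 0 of 16408, with 1347 at an unadjusted p under 0.05. In 1000 kb windows it called 0 of 2481, with 240 at an unadjusted p under 0.05. No other tool was run on windows.

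Libraries did not separate cleanly by subpopulation. The mean Pearson correlation across peaks was 0.946 for the 12 pairs within groups and 0.943 for the 16 pairs between groups (difference 0.00273, one-sided exact permutation p = 0.0857). The highest correlation of any pair, 0.959, was between replicate 1 of Vwf+Gata1+ cells and replicate 1 of Vwf-Gata1+ cells. The first 3 principal components held 22.6%, 18.1% and 16.1% of the variance. Only the third separated the groups, at an exact permutation p of 0.0286, the smallest possible, and 0.229 after adjustment over 8 tests.

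**Figure D3:**
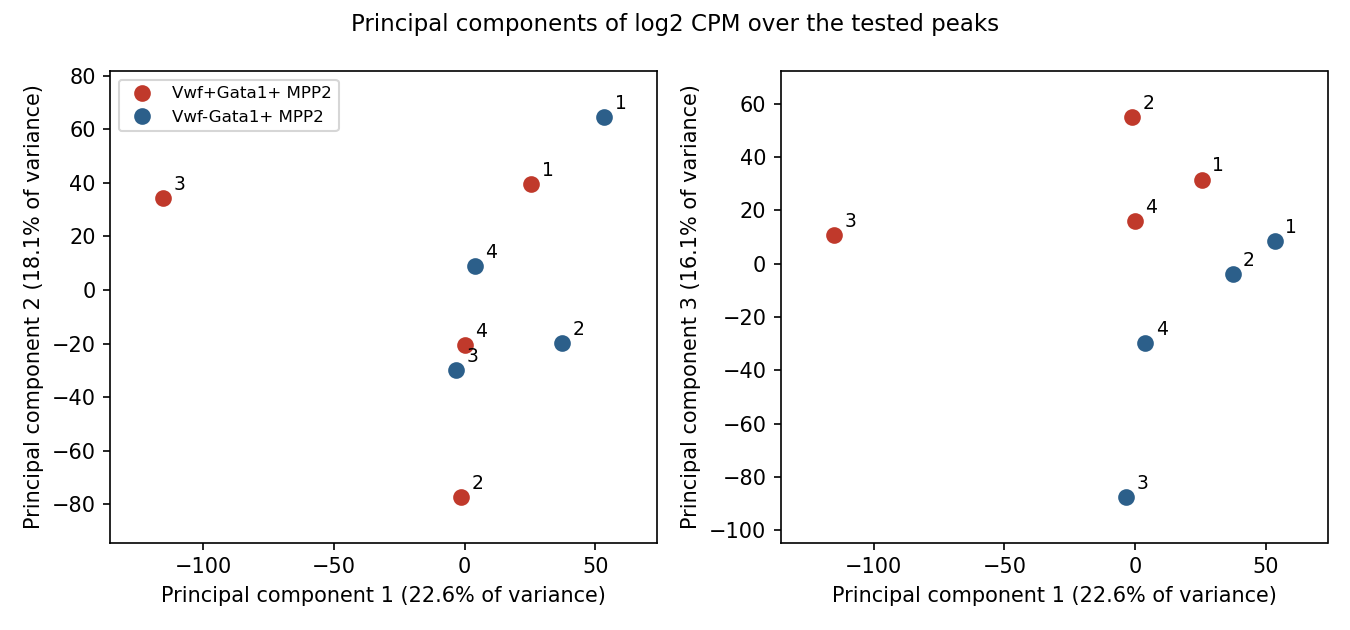
Principal components of log2 CPM over the tested peaks, component 1 against components 2 and 3 (unitless scores); each point is a library, coloured by subpopulation and numbered by replicate. Component 3, with 16.1% of the variance, is higher in all 4 Vwf+Gata1+ libraries than in any Vwf-Gata1+ library, whereas components 1 and 2 mix the groups.

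The count of called peaks was 71, 4, 5 and 7 without replicates 1, 2, 3 and 4 of Vwf+Gata1+ cells, and 3, 5, 52 and 10 without replicates 1, 2, 3 and 4 of Vwf-Gata1+ cells. Each of the 14 calls was lost without at least 1 library: the chromosome 10 peak kept its call in 7 of these 8 fits, the peak at 60250097 to 60250603 on chromosome 11 in 1 and the peak of chromosome 16 in 2. The log2 fold changes of the 14 moved by at most 22.1% in these fits. DESeq2 called 11 peaks, of which 10 were among the 14, while limma-voom with quality weights called 0, with 7236 at an unadjusted p under 0.05.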

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

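The 14 called peaks had the same direction in each of the 19 other fits, and 0 values reversed. The groups do not overlap at these peaks, which were picked from the same libraries, so a reversal was hardly possible. The shared direction is therefore no separate support. The calls themselves often did not hold: of 266 values for these peaks in the other fits, 179 stayed past the threshold, and without 1 library a peak kept its call in 1 to 7 of 8 fits. The log2 fold changes stayed at 0.814 to 1.22 of their size, and at 0.913 to 1.15 with limma-voom, which kept no call. The number of peaks called, 13 higher and 1 lower in Vwf+Gata1+ cells, did depend on the processing, and the cause was not tested unless stated. RLE scaling, no filter and the CPM minimum each gave 12 and 1, and autosomes only gave 13 and 1. Total count scaling gave 21 and 6, loess offsets 27 and 7, DESeq2 11 and 0 (3372 peaks at an unadjusted p under 0.05), and limma-voom with quality weights 0 and 0 (7236 at an unadjusted p under 0.05). An adjusted p under 0.01 gave 0 and 0, and one under 0.1 gave 48 and 12, by construction. A fold of at least 2 as well gave 9 and 1. Of the fits chosen after seeing the data, a term for replicate 1 gave 169 and 42, and the share of counts in the strongest 1% of peaks as a covariate gave 33 and 15.

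Leaving out 1 library gave between 3 and 62 higher peaks and between 0 and 9 lower peaks. The highest totals were 71 without replicate 1 of Vwf+Gata1+ cells and 52 without replicate 3 of Vwf-Gata1+ cells, and the lowest was 3 without replicate 1 of Vwf-Gata1+ cells.

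With the replicate number as a block, 375 peaks were higher and 136 lower, and these included all 14. No label says what a shared number means. Deviations from the group means correlated at 0.301, 0.163, 0.074 and 0.0103 for replicates 1 to 4, so not all exceeded 0.1. Of the 8 libraries, 5 correlated best with their own number, a hint from the data and not the design.

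Runs of 3 called peaks were not possible at any gap, with at most 2 called peaks on a chromosome. Within signal classes, with at most 7 called peaks in one, no width class passed (lowest unadjusted p of Fisher's exact test 0.233). The alternatives for gene lists, promoter peaks and motifs were not run, since peaks were not assigned to genes here. Depth limits the weak peaks most: the median standard error of the log2 fold change was 0.33 in the weakest signal class and 0.14 in the strongest.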

Other observations

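The count of splits, the test of scaling, the test of the lean with a covariate, the covariate itself, the test of a lean to one side, the relation of chromosome X to depth, and the measures on peaks at an unadjusted p under 0.01 or 0.001 were chosen only after the results they bear on were seen.

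Below the threshold, some neighbouring peaks leaned to the same side. Taking peaks at an unadjusted p under 0.01, 7 runs of 3 or more higher peaks and 5 runs of lower peaks lay within gaps of 50 kb, against means of 2.44 and 1.17 in 1000 random draws of as many peaks (permutation p = 0.012 and 0.005). The excess depended on the gap. At 20 kb there were 1 and 1 (permutation p = 0.415 and 0.198). At 100 kb there were 22 and 10, against means of 7.73 and 3.84 (permutation p = 0.001, the smallest the draws can give, and 0.005). Besides their own members, the 12 runs at 50 kb spanned 74 tested peaks, of which 46 (62.2%) went in the direction of the run. In a 43.9 kb stretch of chromosome 6 (mm9, 125490694 to 125534555), 9 of 12 tested peaks were higher in Vwf+Gata1+ cells, or 6 of 9 without the 3 that make the run. The 3 peaks of its run had log2 values of 0.37 ± 0.11, 0.56 ± 0.18 and 0.51 ± 0.11 (SE), and the last had 37.5 ± 5.99 CPM against 26.2 ± 3.61 CPM (SD, n = 4 each; edgeR adjusted p = 0.113). On chromosome 19 (7184029 to 7254017), 11 of 14 tested peaks were higher, or 7 of 10 without the run. A run on chromosome 11 (117801001 to 117841382) had 4 of 10 besides its members. Of the lower runs, one on chromosome 8 spanned 5.63 kb (8983234 to 8988865), with log2 values of -1.10 ± 0.27, -0.43 ± 0.12 and -1.08 ± 0.32. The 1 other tested peak in it was not lower (log2 0.11 ± 0.36). No peak of these runs passed the adjusted threshold, and the regions were chosen after their values were seen. Genes at these regions were not looked up, so it is not known here whether any lies at Vwf or Gata1. The sort itself selects for a difference in Vwf, while both groups were sorted as positive for Gata1. Vwf is a gene of mouse chromosome 6, so this doubt bears most on the region of chromosome 6.

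Peaks at an unadjusted p under 0.001 are picked by a test with more power at strong peaks, so a shortage of weak and narrow peaks among them is no finding about the cells. Their signal and width were compared with those of the other tested peaks, with 33.3% of tested peaks in each of 3 equal classes (Fisher's exact test over peaks, 54 tests). Of the 212 higher peaks, 20.3% were in the weakest signal class and 43.4% in the strongest (adjusted p = 0.00106 and 0.0291), and 18.9%, 45.3% and 35.8% in the narrowest, middle and widest width class (adjusted p = 0.000196, 0.00594 and 0.968). Of the 115 lower peaks, 20.9% were in the narrowest and 47.8% in the widest (adjusted p = 0.0358 and 0.0193), and no signal class passed (lowest adjusted p = 0.319). Peaks are not independent replicates.

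Chance cannot be excluded for the 14 called peaks. Of the 35 splits of the 8 libraries into 4 and 4, 3 gave 14 or more peaks, the real one included, and the highest of the others gave 76. The split with 76 peaks exchanges only 1 library of each group in the real split, so a difference from the sort can add to its count. Another, with 16 peaks, set replicates 1 and 2 of both groups against replicates 3 and 4. Both of these kept the replicate 1 libraries of the 2 groups on one side. Of the 20 splits that part them, as the real one does, the others called at most 1 peak, a subset chosen after the counts were seen.

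The 76 peaks may come from a structure of the libraries other than the sort, from the sort, or from both. That split set replicate 1 of Vwf+Gata1+ cells and replicates 1, 2 and 4 of Vwf-Gata1+ cells against the rest. Of its 76 peaks, 74 were higher in the rest, which held the other Vwf+Gata1+ libraries. The real comparison called 71 peaks without the exchanged Vwf+Gata1+ library and 52 without the exchanged Vwf-Gata1+ library. The split with 76 peaks was the only one in which the share of counts in the strongest 1% of peaks did not overlap, with means of 10.8% and 11.8% (difference 0.933 percentage points). Of its 76 peaks, 96.1% were in the strongest signal class, which is consistent with a difference in signal to background between libraries, although strong peaks also give the test more power. Each side held only 1 library of one group, so within a side that group has no replicate. A fit with the side as a term was not run, and a covariate was used instead.

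The lean toward higher signal in Vwf+Gata1+ cells, 13 of 14 called peaks and 64.8% of peaks at p under 0.001, stays open to several technical explanations. Scaling cannot be told apart: under the 3 other scalings at least 77.8% of called peaks and 57.8% (total count) to 65.7% (RLE) of peaks at p under 0.001 were higher, but these moved the log2 fold changes of the 14 too little to test it. With the covariate, the 14 log2 fold changes kept a median of 0.924 of their size. This argues only against the covariate as the source of most of their size. It is a weak test, since the groups differed little in the covariate and the 14 were picked from these data. The peak of chromosome 16, with the highest signal of the 14, fell the most relative to its size, from 0.59 to 0.48 (a ratio of 0.82). A difference in signal to background stays open for the lean. With the covariate 53.8% of peaks at p under 0.001 were higher. That share fell because lower peaks rose from 115 to 217, while higher ones rose from 212 to 253. A single library may carry part of the lean, since without replicate 3 of Vwf+Gata1+ cells, the shallowest, 53.4% of such peaks were higher (126 against 110), in a range up to 73.5%. Of 35 splits, 16, the real one included, had as large a share of such peaks on one side, although only 3 had as many, and a biological difference stays open and was not tested.

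Runs of neighbouring peaks, 12 in the real split or 6.89 per 1000 peaks at p under 0.01, also came with other groupings of the libraries. Of the 35 splits, 8 gave as many per 1000 peaks, the real one included, and the highest of the others gave 12.7. The other 7 all had both replicate 1 libraries on one side, as 15 of the 35 splits do. The real split parts these libraries, and the others of the 20 splits that do so had at most 4 runs and at most 5.57 per 1000 peaks, a subset chosen after the counts were seen. A biological difference between the subpopulations at single regions stays open and was not tested.

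Both replicate 1 libraries, the deepest of the 8, had the smallest shares of counts on chromosome X. The share was 1.81% (95% exact binomial interval 1.80% to 1.82%) in Vwf+Gata1+ cells and 1.77% (1.76% to 1.78%) in Vwf-Gata1+ cells, and it was 1.89% to 1.93% in the other 6 libraries. The gap between them, 0.077 percentage points, exceeded the range of the other 6, 0.037. Over all 8, the share and the total count had a Pearson r of -0.653 (exact permutation p = 0.0756). Spearman rho was -0.738 (exact permutation p = 0.0458), and both p were 0.0756 after adjustment over 2 tests. The replicate 1 libraries, which stand apart, may carry this relation. Within the 6, the share and the total count had a Pearson r of -0.264 (exact permutation p = 0.625) and a Spearman rho of -0.429 (exact permutation p = 0.419), both 0.625 after adjustment over 2 tests, and r was -0.439 without the 2 libraries farthest in depth. Depth as the reason for the low share in replicate 1 therefore stays open. Of 46 sets of 4 values tested for a library far from the rest with Dixon's test, none passed, where chance gives about 1 in 20.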
